A study of Oryza sativa with 6 samples.

How the data were processed

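RNA sequencing of leaf blades was compared between 3 Oshmgb1 and 3 WT libraries of rice, made from seedlings grown under HP conditions for 28 days in a greenhouse. Per the labels, total RNA was extracted with a Macherey-Nagel plant RNA kit and libraries were built with the NEBNext Ultra RNA kit, and bcl2fastq 2.19, HISAT2 2.0.5 and StringTie 1.3.6 were used, without their roles. The genome build and the counting tool were not given in the sources used here. The ATAC-seq part of the study was not analysed here.

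The authors deposited counts and fold changes for 56584 genes with MSU-style identifiers (LOC_Os) and assembled loci (MSTRG). The table holds whole-number counts per library as deposited, which were the values analysed here. It also holds FPKM per library, computed by the authors from gene length and the column total of the same table. The authors' group means are FPKM means in which 0 was replaced by a small constant, and the authors' fold change is the log2 ratio of these means. The p-value columns, a p-value and an FDR per gene, were computed by the authors with a test that was not stated. Symbols in the table are based on homology, so that some name a gene of another family. Locus numbers and clone names were not counted as informative descriptions.

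Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and data.table (version 1.17.8). Genes were kept with filterByExpr, which left 20913 of 31357 genes with any count, and libraries were scaled with TMM (factors 0.981 to 1.03). A robust quasi-likelihood F test in edgeR with genotype as the only term gave 2-sided p-values, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are Oshmgb1 over WT. The SE of a log2 fold change is its size divided by the square root of F, and group values are means of TMM-normalised CPM with their SD over 3 libraries. For genes with 0 counts in a whole group, folds were computed over a floor of 3 counts for the group. For 1 to 6 counts in a group, the ratio of counts scaled by library size and TMM factor has an exact 95% interval. Total counts per library ran from 15890000 to 18016457. Replicate numbers did not pair the libraries, and no batch was given in the labels.

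The design, the alternatives, the rule for named genes and 32 gene lists were fixed before the data were examined. The lists were Pi signalling, Pi transport, Pi scavenging, membrane lipid remodelling, HMG-box proteins, histones, light harvesting and photosystems, Calvin cycle, chlorophyll synthesis, chlorophyll breakdown and senescence, cytosolic ribosomal proteins, heat shock proteins and chaperones, pathogenesis-related proteins, diterpenoid phytoalexins, WRKY factors, jasmonate, auxin response, gibberellin, cytokinin, abscisic acid and dehydration, ethylene response, cell wall expansion, cell cycle and DNA replication, circadian clock, nitrogen transport and assimilation, iron homeostasis, sugar transport and sucrose synthesis, transposon-related genes, meristem and flower, root, guard cell and epidermis, and organelle-encoded transcripts. Members were matched by words in the symbol or description and, for some lists, by identifiers. Matches by name alone also brought in genes of other families, and an added alternative removed them. Lists with at least 5 tested members were tested with camera (limma), 2-sided, with a preset correlation of 0.01, and adjusted over the 30 lists tested. Members were also adjusted over the list alone.

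Named genes were OsHMGB1, the 8 changed genes with the highest and the 8 with the lowest log2 fold change among those without overlap between the groups, with a mean of at least 5 CPM in the higher group and an informative name, the 4 members with the smallest p of each of the 4 Pi and lipid lists, and the 3 with the smallest p of each other list that passed or had at least 3 changed members. Counts of named genes cover all genes under this rule, though not every one is printed. GO and KEGG terms of the deposited table with 10 to 500 tested genes were tested with 1-sided Fisher's exact tests against the tested genes with any term of that kind, 17154 for GO and 4541 for KEGG, with adjustment over 336 tests.

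Alternatives were DESeq2 size factors in edgeR, library size alone, no low-count filter, a mean CPM of at least 1, DESeq2, limma-voom, limma on log2(FPKM + 1) and on log2(FPKM + 0.1), the replicate number as a block, each library left out in turn, an adjusted p under 0.01, a change of at least 2-fold, camera with an estimated correlation, and fry. The fit was tested on simulated data with the depths and dispersions of these libraries and 200 changed genes. With dispersions per gene, 32.8%, 58.2% and 92.1% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, and 12.6% of 135 calls were false. With dispersions that followed the trend with expression, these were 24.6%, 74.6% and 98.4%, with 3.73% of 134 calls false. Of 100 lists without change none passed in either run. The simulated genes varied independently of one another, so this does not cover lists whose genes vary together. In DESeq2, 25.1% of 167 calls and 3.97% of 126 calls were false in these 2 runs. The reference annotation available here holds no LOC_Os identifiers, so that no coordinates are given.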

Results

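Transcript levels were measured by RNA sequencing in leaf blades of rice (Oryza sativa) seedlings grown under HP conditions for 28 days. The labels do not spell out HP, and the title of the series names phosphate homeostasis. There were 2 genotypes, wild type (WT) and the mutant Oshmgb1, with 3 libraries each. Total counts were 17214163, 15890000 and 16707541 in WT 1, 2 and 3. They were 18016457, 17086244 and 16400342 in Oshmgb1 1, 2 and 3. Between 26402 and 27261 genes per library had at least 1 count, and the 10 most abundant genes took 7.2% to 8.15% of the counts. Across genes, which are not independent replicates, correlations of log2 values lay between 0.976 and 0.985 for libraries of the same genotype and between 0.959 and 0.975 for libraries of different genotypes. In multidimensional scaling, which places libraries by the distance between their profiles, dimension 1 (48.3%) separated the genotypes. Dimension 2 (20.6%) set WT 2 (-0.806) and Oshmgb1 1 (-1.05) apart from the other libraries (0.187 to 0.73). Deviations from the group means correlated at 0.39 between these 2 libraries, the highest value between genotypes. The cause was not tested. The labels do not say whether the libraries came from separate plants, so the p-values measure the spread between these libraries only. Intervals and floors cover counting error only.

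The comparison of Oshmgb1 with WT asks which leaf transcripts differ when OsHMGB1, a chromatin protein of the high mobility group, is mutated. The transcript of OsHMGB1 itself (LOC_Os06g51220, listed in the deposited table with the symbol HMGB2) fell from 908 ± 25.3 CPM (read count normalised to library size, SD, n = 3) in WT to 143 ± 6.42 CPM (SD, n = 3) in Oshmgb1, a 6.36-fold lower level. Its log2 fold change was -2.67 (SE 0.065, adjusted p = 4.37e-07), and all 3 Oshmgb1 libraries lay below all 3 WT libraries. Lists of pathogenesis-related proteins, WRKY factors and jasmonate genes were shifted down in camera with a preset correlation, though with an estimated correlation the adjusted p was 0.414, 0.716 and 0.716. Genes of cysteine and methionine metabolism were enriched among those that rose. Of the phosphate (Pi) signalling genes none passed, and of the Pi transport list 2 did, of which 1 is described as a transporter.

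Of 20913 genes tested, 843 (4.03%) changed, 315 of them higher and 528 lower in Oshmgb1. A change of at least 2-fold was found for 300 genes, 79 higher and 221 lower. The 3 Oshmgb1 values lay all above or all below the 3 WT values for 26.4% of the tested genes, where chance gives 10%, and for all 843 changed genes. With library size as the only scaling, 235 genes were higher and 632 lower, so that 27.1% of the calls were higher in place of 37.4%, and with FPKM values in limma 27.2% were. The number of changed genes was 216 without WT 1, 563 without WT 2, 226 without WT 3, 649 without Oshmgb1 1, 356 without Oshmgb1 2 and 392 without Oshmgb1 3. Of the 55 named genes past the threshold, 22 also passed in each of the 6 fits that left out 1 library.

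**Figure D1:**
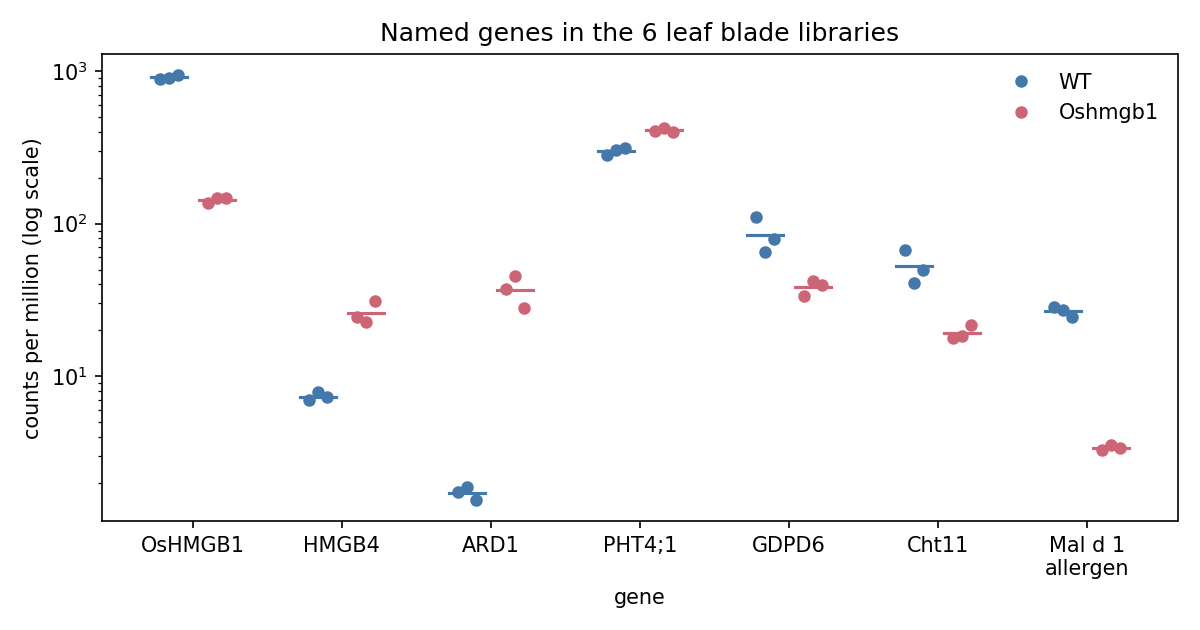
Normalised read counts (CPM, log scale) of 7 named genes in the 3 WT and 3 Oshmgb1 libraries, with each point a library and each line a group mean. OsHMGB1 lay between 135 and 147 CPM in Oshmgb1 and between 887 and 936 CPM in WT, and for each gene the libraries of the genotypes did not overlap.

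Among the named genes with the highest fold changes, a pair described as hAT family dimerisation domain proteins, a domain known from hAT transposases, had reads in Oshmgb1 alone. LOC_Os11g39660 had 0 counts in each WT library and 17.9 ± 3.29 CPM (SD, n = 3) in Oshmgb1, at least 300-fold higher over a floor of 3 counts for the WT group (adjusted p = 0.000122). LOC_Os08g23200 likewise had 0 WT counts and 5.94 ± 1.01 CPM (SD, n = 3) in Oshmgb1, at least 99.5-fold higher (adjusted p = 0.000808). ARD1 (LOC_Os10g28350), an acireductone dioxygenase of the methionine salvage cycle, rose from 1.73 ± 0.173 to 36.9 ± 8.51 CPM (SD, n = 3), with a log2 fold change of 4.41 (SE 0.209, adjusted p = 8.85e-05). An F-box domain gene (LOC_Os10g41838, symbol At5g62510) rose with a log2 fold change of 5.04 (SE 0.271, adjusted p = 8.85e-05), and TRN2 (LOC_Os03g01012), described as a TORNADO 2-like protein, with 2.91 (SE 0.285, adjusted p = 0.0019). Tf2-12 (LOC_Os12g24050), RGA2 (LOC_Os11g45180) and RE1 (LOC_Os04g18770) rose with log2 fold changes of 7.52, 3.47 and 3.25. These calls were not kept in every fit that left out 1 library. Tf2-12 did not pass without WT 1 (adjusted p = 0.0809) or WT 3 (0.0634). RGA2 did not pass without WT 1 (0.109), WT 2 (0.0764) or WT 3 (0.0984), nor RE1 without WT 1 (0.0916) or Oshmgb1 2 (0.0541). In limma-voom, Tf2-12 and RGA2 had adjusted p = 0.147 and 0.1, and RGA2 had adjusted p = 0.0651 with log2(FPKM + 1) in limma.

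The named genes with the lowest fold changes included 2 wall-associated receptor kinases, a protein class that spans the plasma membrane and binds the cell wall. WAK1 (ChrSy.fgenesh.gene.14) fell from 25.3 ± 3.56 to 3.40 ± 1.15 CPM (SD, n = 3) and WAK4 (MSTRG.5817) from 20.9 ± 4.11 to 2.83 ± 0.377 CPM (SD, n = 3), with log2 fold changes of -2.90 (SE 0.241, adjusted p = 0.00191) and -2.88 (SE 0.178, adjusted p = 0.000165). A gene described as mucin-5AC (LOC_Os01g23710) fell 9.46-fold, from 18.2 to 1.92 CPM (adjusted p = 5.66e-05), and a gene described as major allergen Mal d 1 (LOC_Os08g28670) fell 7.87-fold, from 26.8 to 3.39 CPM (adjusted p = 8.91e-06). ADH2 (LOC_Os11g10520), an alcohol dehydrogenase, the RIR1a protein gene (LOC_Os10g41980) and AED3 (LOC_Os10g39300), an aspartic protease, fell with log2 fold changes of -2.55, -2.22 and -2.18. The largest adjusted p of these 7 genes in any fit that left out 1 library was 0.0398, for LOC_Os10g41980.

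Of 17 tested genes of Pi signalling, which holds the SPX proteins that sense Pi status and the PHR factors that they bind, none passed in edgeR with all 6 libraries and genotype as the only term, either over all genes or adjusted over the list alone. OsNLA1 (LOC_Os07g47590), a ubiquitin ligase, had the smallest p, with a log2 fold change of -0.41 (adjusted p = 0.0961). It was followed by SPX-MFS3 (LOC_Os06g03860) with 0.32 (adjusted p = 0.107), SPX-MFS2 (LOC_Os02g45520) with 0.69 (adjusted p = 0.143) and OsPHR3 (LOC_Os02g04640) with -0.51 (adjusted p = 0.154). SPX-MFS2 passed in DESeq2 (adjusted p = 0.00285) and in edgeR with the replicate number as a block (0.0185), and SPX-MFS3 passed without Oshmgb1 3 (adjusted p = 0.0402). For the calls gained in DESeq2, here and below, 25.1% of its calls were false in simulated data with dispersions per gene, against 12.6% in edgeR (3.97% and 3.73% with dispersions that followed the trend). The list as a whole had a median log2 fold change of 0.05 (adjusted p = 0.319).

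Among 21 tested genes of the Pi transport list, 2 were higher and 0 lower over all genes, against 4 higher and 2 lower adjusted over the list alone. PHT4;1 (LOC_Os01g17240), an anion transporter of the chloroplast, rose from 300.1 ± 15.1 to 407 ± 11.9 CPM (SD, n = 3), with a log2 fold change of 0.44 (SE 0.0622, adjusted p = 0.0085). The other, LOC_Os08g43040, carries the symbol PHT1 and is described as a hydroxycinnamoyltransferase, an enzyme of phenolic metabolism and not a transporter. Its log2 fold change was 0.38 (adjusted p = 0.0264), and it did not pass without WT 1 (0.0842), WT 2 (0.0745), WT 3 (0.0996), Oshmgb1 1 (0.0556), Oshmgb1 2 (0.0785) or Oshmgb1 3 (0.0612). OsPHO1;3 (LOC_Os06g29790), of the Pi exporter family, had a log2 fold change of -0.55 (adjusted p = 0.0579) and passed without Oshmgb1 2 (0.0493), with library size alone (0.0459), without a filter (0.0153) and in DESeq2 (0.0211). OsSPDT (LOC_Os06g05160) had 0.37 (adjusted p = 0.075). The list had no common direction, with a median of -0.01 while the test pointed up (adjusted p = 0.89).

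The Pi scavenging list had 34 tested members, of which 4 fell and 0 rose, both over all genes and adjusted over the list alone. Of these 4, 3 were receptor kinases that carry a phosphodiesterase name in their description, LOC_Os01g02370, LOC_Os01g02730 and LOC_Os01g02700, with log2 fold changes of -1.44, -2.15 and -0.76. GDPD6 (LOC_Os03g40670), a glycerophosphodiester phosphodiesterase, fell from 84.8 ± 22.9 to 38.4 ± 4.36 CPM (SD, n = 3), with a log2 fold change of -1.14 (SE 0.207, adjusted p = 0.0429). LOC_Os01g02700 did not pass without WT 1 (0.111), WT 3 (0.12), Oshmgb1 1 (0.0685), Oshmgb1 2 (0.111) or Oshmgb1 3 (0.0539). GDPD6 did not without WT 3 (0.119), Oshmgb1 1 (0.129), Oshmgb1 2 (0.115) or Oshmgb1 3 (0.125) or without a filter (0.103). The list was shifted down with a median of -0.06 (camera, adjusted p = 0.00861). It had adjusted p = 0.414 with an estimated correlation, 0.0848 without Oshmgb1 1, and 0.0726 with log2(FPKM + 1), and passed in fry (0.0253). Without 13 genes that share only a name with Pi scavenging, 23 members were tested, 1 fell, and the adjusted p was 0.114. Of 16 tested genes of membrane lipid remodelling, which replaces phospholipids with galactolipids and sulfolipids, none passed in edgeR, over all genes or adjusted over the list alone. Log2 fold changes were 0.21 for DGD2 (LOC_Os03g16140), 0.35 for LOC_Os01g04920, 0.13 for OsSQD2 (LOC_Os07g01030) and 0.16 for OsSQD1 (LOC_Os05g32140). The list had an adjusted p of 0.482.

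The HMG-box list, the family of the mutated gene, had 1 member that rose and 2 that fell among 11 tested (2 and 2 adjusted over the list alone). HMGB4 (LOC_Os09g37910) rose 3.53-fold, from 7.37 ± 0.465 to 26.01 ± 4.49 CPM (SD, n = 3), with a log2 fold change of 1.82 (SE 0.137, adjusted p = 0.000617), and passed in each of the 6 fits that left out 1 library. Besides OsHMGB1, wdhd1 (LOC_Os09g06560), a protein with WD repeats and an HMG box, fell from 5.75 to 3.08 CPM with a log2 fold change of -0.90 (adjusted p = 0.0235). It did not pass without WT 1 (0.101), WT 2 (0.0681), WT 3 (0.0557), Oshmgb1 2 (0.0659) or Oshmgb1 3 (0.0762), nor with log2(FPKM + 1) (0.0794). The shift of the list (camera, Down, adjusted p = 0.00861) had adjusted p = 0.414 with an estimated correlation and 0.0294 in fry. It missed the threshold without Oshmgb1 1 (0.0848), Oshmgb1 2 (0.101) or Oshmgb1 3 (0.0506) and in limma-voom (0.852). Without OsHMGB1 itself and 4 genes of other families, the test pointed up (adjusted p = 0.133).

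Of 30 lists tested, 9 passed in camera, 3 higher and 6 lower, and the other 9 splits of the 6 libraries gave up to 10 lists. The defence-related lists that passed were lower in Oshmgb1. Pathogenesis-related proteins had a median log2 fold change of -0.27 over 79 tested genes (adjusted p = 0.000187, and adjusted p = 0.414 with an estimated correlation), with 0 higher and 4 lower (0 and 7 adjusted over the list alone). The chitinases, enzymes that break down chitin of fungal cell walls, Cht11 (LOC_Os03g04060), CHIT3 (LOC_Os01g49320) and LOC_Os10g28080 fell with log2 fold changes of -1.45, -0.80 and -0.79. Cht11 went from 52.6 ± 13.6 to 19.3 ± 2.16 CPM (SD, n = 3). Cht11 did not pass without WT 3 (0.0607), Oshmgb1 1 (0.0644) or Oshmgb1 2 (0.072), and CHIT3 did not without WT 1 (0.0691), WT 3 (0.0821) or Oshmgb1 3 (0.0617). LOC_Os10g28080 passed only without Oshmgb1 3 (0.0673 to 0.123 without any other library). WRKY factors, transcription factors of stress and defence responses, had a median of -0.23 over 63 genes (adjusted p = 0.00718, and adjusted p = 0.716 with an estimated correlation), with 0 higher and 3 lower (0 and 5 adjusted over the list alone). WRKY70 (LOC_Os03g21710), WRKY54 (LOC_Os07g48260) and WRKY42 (LOC_Os01g18584) fell with log2 fold changes of -2.16, -0.98 and -0.45. The WRKY shift missed the threshold without WT 1 (0.0544), WT 3 (0.0919) or Oshmgb1 1 (0.177), as did WRKY70 without WT 1 (0.0588). WRKY54 did not pass without WT 1 (0.125), WT 3 (0.105), Oshmgb1 1 (0.0598) or Oshmgb1 2 (0.102), and WRKY42 without any 1 of the 6 libraries (0.0522 to 0.119).

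Jasmonate genes, which make or answer a hormone of wounding and defence, had a median of -0.38 over 39 tested genes (adjusted p = 0.00769, and adjusted p = 0.716 with an estimated correlation), with 1 higher and 2 lower (2 and 4 adjusted over the list alone). TIFY6A (LOC_Os12g41560), of the JAZ repressor family, fell from 19.5 ± 2.46 to 10.9 ± 2.03 CPM (SD, n = 3), and OPR1 (LOC_Os06g11280), described as an oxophytodienoate reductase, fell from 2.48 to 0.923 CPM. LOX2.3 (LOC_Os02g10120), a chloroplast lipoxygenase, rose from 316.7 ± 19.97 to 393 ± 18.1 CPM (SD, n = 3). Diterpenoid phytoalexins, antimicrobial compounds of rice, had a median of -0.33 over 44 genes (adjusted p = 0.0295, and adjusted p = 0.716 with an estimated correlation), with 0 higher and 2 lower (0 and 2 adjusted over the list alone). KSL5 (LOC_Os02g36220) fell from 5.90 ± 1.24 to 1.79 ± 0.123 CPM (SD, n = 3), CYP71Z6 (LOC_Os10g30410) fell 1.91-fold, and CYP701A6 (LOC_Os06g37364), an ent-kaurene oxidase, had a log2 fold change of 0.29 (adjusted p = 0.0689). The jasmonate shift missed the threshold without WT 3 (0.0558) or Oshmgb1 1 (0.134). The diterpenoid shift missed it without WT 1 (0.0633), WT 2 (0.0745), Oshmgb1 1 (0.135) or Oshmgb1 2 (0.0979), with library size alone (0.0763) and with log2(FPKM + 1) (0.0996). TIFY6A did not pass without WT 2 (0.0725), WT 3 (0.1) or Oshmgb1 2 (0.0615), and CYP71Z6 did not without WT 1 (0.0777) or WT 3 (0.0694). OPR1 passed only without Oshmgb1 1 (0.0881 to 0.125 without any other library) and LOX2.3 only without WT 2 (0.0532 to 0.151). LOX2.3 had 0.0607 with library size alone.

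The lists that were higher in Oshmgb1 shifted by little with TMM, which the medians below use. With DESeq2 size factors in edgeR, the medians of ribosomal proteins, histones and light harvesting were 0.115, 0.105 and 0.101. With library size alone, they were lower, at 0.0733, 0.0625 and 0.0623. In limma on log2(FPKM + 1) they were 0.0751, 0.0458 and 0.0589. In these last 2 settings the median of all tested genes moved down as well, to -0.042 and -0.0361. Cytosolic ribosomal proteins had a median of 0.12 over 183 tested genes, 149 of them with a positive log2 fold change (camera, adjusted p = 2.94e-05, and adjusted p = 0.716 with an estimated correlation), with 6 higher and 0 lower (5 and 0 adjusted over the list alone). RPL24 (LOC_Os05g40820) and RPL28A (LOC_Os01g51020) rose with log2 fold changes of 0.31 and 0.80. Histones had a median of 0.11 over 40 genes (adjusted p = 0.00238, and adjusted p = 0.716 with an estimated correlation), with 2 higher and 0 lower (8 and 0 adjusted over the list alone). A histone H2A gene (LOC_Os07g36140) rose from 51.8 ± 3.45 to 77.5 ± 4.70 CPM (SD, n = 3), and a linker histone H1 gene (LOC_Os07g08710) rose from 100.2 ± 19.4 to 174 ± 10.7 CPM (SD, n = 3). The H4 gene LOC_Os01g61920 had a log2 fold change of 0.36 (adjusted p = 0.0717, 0.0425 without WT 2 and 0.0405 without a filter). Light harvesting and photosystem genes had a median of 0.10 over 55 genes (adjusted p = 0.00528, and adjusted p = 0.716 with an estimated correlation), with 0 past the threshold over all genes and 0 adjusted over the list alone in edgeR with the low-count filter. HCF136 (MSTRG.18726), an assembly factor of photosystem II, had 0.32 (adjusted p = 0.0559, 0.0175 in edgeR without a filter and 0.0166 in DESeq2). PSBP (LOC_Os07g04840) had 0.25 (0.104, and 0.0484 in DESeq2) and PSAF (LOC_Os03g56670) had 0.25 (0.111). Without WT 3, the histone and photosystem shifts missed the threshold (0.0808 and 0.0738). RPL24 passed only without Oshmgb1 1 (0.062 to 0.0953 without any other library), LOC_Os07g08710 only without WT 2 (0.0512 to 0.0871), and RPL28A in none of the 6 fits that left out 1 library (0.069 to 0.133).

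**Figure D2:**
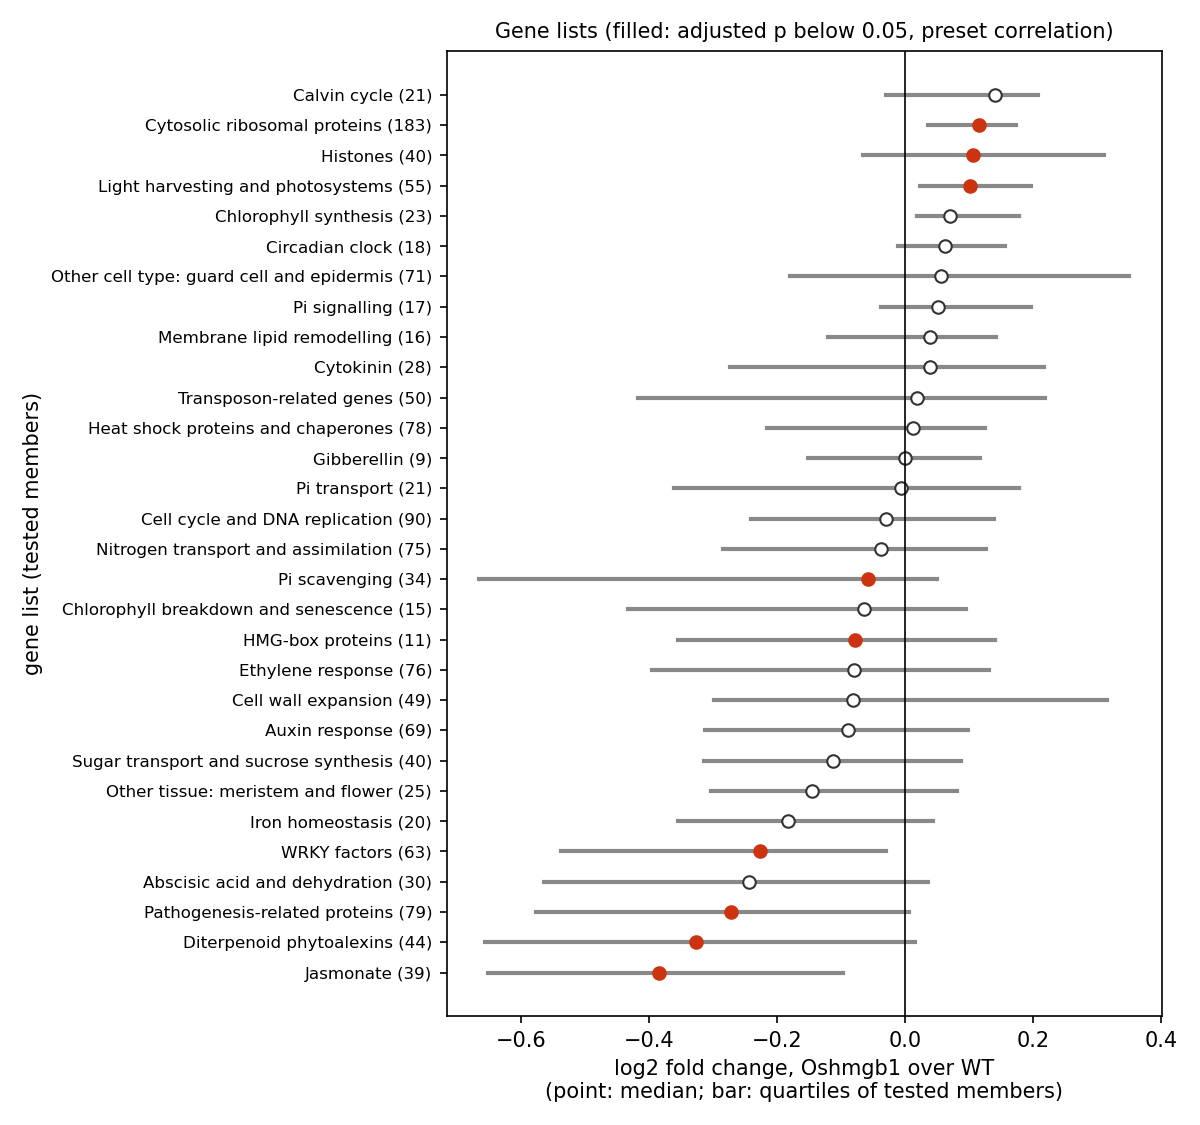
Median log2 fold change (Oshmgb1 over WT, points) and quartiles (bars) of the tested members of the 30 gene lists, with the number tested in parentheses and filled points for lists with an adjusted p below 0.05 in camera with a preset correlation. The jasmonate list had the lowest median, -0.38, and the medians of the lists called higher lay between 0.10 and 0.12; the call of no list held with an estimated correlation.

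Of the lists that did not pass in camera, 5 had at least 3 changed members. Sugar transport and sucrose synthesis had 1 higher and 6 lower of 40 (1 and 8 adjusted over the list alone, list adjusted p = 0.0906). CINV1 (LOC_Os02g03320) and CIN1 (LOC_Os02g33110), both invertases, which split sucrose, fell with log2 fold changes of -1.12 and -0.38, and the chloroplast invertase NIN3 (LOC_Os02g32730) rose with 0.28. Nitrogen transport and assimilation had 3 higher and 1 lower of 75 (6 and 6 adjusted over the list alone, list adjusted p = 0.89), among them NPF5.6 (LOC_Os03g60850), which rose from 30.6 ± 1.71 to 47.3 ± 2.35 CPM (SD, n = 3). The others named were NPF5.10 (LOC_Os05g35650), which rose with 0.37, and the ammonium transporter AMT3-2 (LOC_Os03g62200), which fell with -1.33. Heat shock proteins and chaperones had 2 higher and 2 lower of 78 (2 and 2 adjusted over the list alone, list adjusted p = 0.981). CLPB2 (LOC_Os03g31300), a chloroplast chaperone, rose from 234 ± 0.414 to 293 ± 6.35 CPM (SD, n = 3). The 2 that fell, LOC_Os09g29200 and LOC_Os12g02960, are described as glutathione transferases. Chlorophyll breakdown and senescence had 1 higher and 2 lower of 15 (1 and 4 adjusted over the list alone, list adjusted p = 0.282). The receptor kinases SIRK (LOC_Os09g18594) and LOC_Os09g19160 were lower at -0.72 and -0.78 and PAO (LOC_Os03g05310), a chlorophyll-degrading oxygenase, was higher at 0.37, and lost the call with library size alone (0.33, adjusted p = 0.0688). Transposon-related genes had 1 higher and 3 lower of 50 (1 and 3 adjusted over the list alone, list adjusted p = 0.981). This list lacks the hAT domain genes above and other genes with transposon-type names, and with these, added after the data were seen, 8 were higher and 11 lower of 240. LOC_Os12g12500, of the Pong class, had 0 WT counts and was at least 63-fold higher, LOC_Os01g46320 had 0 Oshmgb1 counts and was at least 34.5-fold lower, and LOC_Os02g17750 fell 3.54-fold.

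In the fits that left out 1 library, NPF5.6, LOC_Os12g12500 and LOC_Os01g46320 passed in all 6. CINV1 did not pass without WT 3 (0.0659) or Oshmgb1 2 (0.0518), nor CLPB2 without WT 1 (0.0666), WT 3 (0.0758) or Oshmgb1 2 (0.0555). SIRK did not pass without WT 1 (0.0922) or WT 3 (0.0895), LOC_Os09g29200 without WT 1 (0.077) or WT 3 (0.0882), and LOC_Os12g02960 without WT 1 (0.0916), WT 3 (0.0659) or Oshmgb1 3 (0.066). NPF5.10 did not pass without WT 1 (0.097), WT 3 (0.0938), Oshmgb1 2 (0.0719) or Oshmgb1 3 (0.0665). AMT3-2 did not pass without WT 1 (0.106), WT 3 (0.0731), Oshmgb1 1 (0.0564) or Oshmgb1 2 (0.0673). CIN1 passed only without Oshmgb1 3 (0.0598 to 0.123 without any other library), PAO only without Oshmgb1 1 (0.102 to 0.16) and LOC_Os02g17750 only without WT 2 (0.085 to 0.165). NIN3 and LOC_Os09g19160 passed in none (0.0585 to 0.122 and 0.0537 to 0.141). In limma-voom, LOC_Os02g17750, LOC_Os09g19160 and PAO had adjusted p = 0.109, 0.0693 and 0.0566. In limma on log2(FPKM + 1), the adjusted p was 0.0741 for LOC_Os09g19160, 0.0979 for PAO, 0.0555 for NIN3 and LOC_Os01g02700, 0.0845 for LOX2.3 and 0.0553 for WRKY54.

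The other lists did not pass in camera. Auxin response had 1 higher and 1 lower of 69 (1 and 1 adjusted over the list alone, list adjusted p = 0.23), with IAA1 (LOC_Os01g08320) higher at 0.66 and ARF15 (LOC_Os05g48870) lower at -0.43. Abscisic acid and dehydration had 0 higher and 2 lower of 30 (0 and 2 adjusted over the list alone, list adjusted p = 0.0547), CYP707A6 (LOC_Os08g36860) and LEA14-A (LOC_Os05g50710). Cytokinin had 1 higher and 1 lower of 28 (1 and 3 adjusted over the list alone, 0.981), RR10 (LOC_Os12g04500) and LOC_Os03g39010. Ethylene response had 1 higher of 76 (0 adjusted over the list alone, 0.657), DCD (LOC_Os02g53330), and gibberellin had 0 of 9 in edgeR (1 higher adjusted over the list alone, 0.882). Calvin cycle genes had 0 past the threshold of 21 in edgeR (0 adjusted over the list alone, 0.0689) and chlorophyll synthesis had 1 higher of 23 (1 adjusted over the list alone, 0.0689), HEMB (LOC_Os06g49110). Circadian clock genes had 0 of 18 (0 adjusted over the list alone, 0.189) and iron homeostasis 0 of 20 in edgeR (1 higher and 3 lower adjusted over the list alone, 0.482). Cell wall expansion had 1 higher of 49 (1 adjusted over the list alone, 0.947), EXPB4 (LOC_Os10g40730), and cell cycle and DNA replication had 1 higher and 1 lower of 90 (0 and 1 adjusted over the list alone, 0.89), CYCA1-1 (LOC_Os01g13260) and KIN14A (LOC_Os01g14090). These single members were named after their values were seen, because so few passed.

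Markers of other tissues and cell types did not pass in camera with the low-count filter used. Meristem and flower genes had 0 higher and 2 lower of 25 (0 and 3 adjusted over the list alone, list adjusted p = 0.0689), MADS26 (LOC_Os08g02070) and MADS57 (LOC_Os02g49840). This list passed, lower, among genes with a mean CPM of at least 1 (adjusted p = 0.0135) and in fry (0.0253). Guard cell and epidermis genes had 0 higher and 2 lower of 71 (0 and 2 adjusted over the list alone, 0.482), At3g26430 (LOC_Os07g39740) and At1g09390 (LOC_Os05g06710), both lipases of the GDSL type. Of the root markers, 3 were tested, too few for a list test, with 0 past the threshold in edgeR (1 lower adjusted over the list alone). No gene of the table could be assigned to the plastid or mitochondrial genomes. The median of a list and the direction of its test had different signs for the Pi transport, gibberellin and transposon-related lists, and the mean and the median had different signs for the cytokinin and heat shock lists, none of which passed.

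Cysteine and methionine metabolism was the only 1 of 336 annotation tests past the threshold, with 10 of its 103 tested genes higher where 1.93 were expected (1-sided Fisher's exact test, adjusted p = 0.00593). SAMDC (LOC_Os09g25620), which makes the aminopropyl donor of polyamine synthesis, rose from 5.03 ± 0.762 to 13.8 ± 2.40 CPM (SD, n = 3). AKHSDH2 (LOC_Os09g12290), an enzyme on the path from aspartate to methionine, rose from 593 ± 69 to 909 ± 82.1 CPM (SD, n = 3). The others were ARD1, ARD4 (LOC_Os10g28360), IDI2 (LOC_Os11g11050) and MTK1 (LOC_Os04g57400) of methionine salvage, the cysteine synthases CAS2 (LOC_Os04g08350) and RCS1 (LOC_Os12g42980), DCD (LOC_Os02g53330) and a malate dehydrogenase (LOC_Os03g56280). Their log2 fold changes ran from 0.29 to 4.41. With genes changed at least 2-fold, the term had 2 genes (adjusted p = 0.871). Then 3 other terms passed, nuclear envelope, epigenetic regulation of gene expression, and flower development, with 4, 4 and 5 higher genes.

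Reads in 1 genotype alone, or nearly so, were found for 22 changed genes. In WT, 18 genes had at most 2 counts per library, 12 of them 0 counts in all 3, and in Oshmgb1 4 genes did. The highest was LOC_Os10g22630, an expressed protein of unknown function, with 1 count in WT and 279 CPM in Oshmgb1, a 14200-fold ratio of normalised counts (exact 95% interval 2550 to 561000). The others with over 5 CPM were MSTRG.3754, LOC_Os08g33550, LOC_Os03g02470, LOC_Os05g43630 and the pair of hAT genes above. MSTRG.3754 and LOC_Os08g33550 had 0 WT counts and were at least 897-fold and at least 490-fold higher. The genes with reads in WT alone or nearly so were LOC_Os01g46320, WAK2 (LOC_Os09g38800), LOC_Os08g37930 and At5g49770 (LOC_Os11g46810), the last with 69 counts in WT and 6 in Oshmgb1, 11.6-fold lower (exact 95% interval 5.05 to 32.6).

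The deposited table holds the authors' own calls on the same libraries, so that the overlap is not independent evidence. They called 1051 genes, 398 higher and 653 lower, of which 1034 were tested here. Of the 843 genes called here, 766 were among them, all with the same sign, while 268 tested genes were called by the authors alone and 77 here alone. At a change of at least 2-fold, 279 genes were shared by 396 and 300. Across tested genes, which are not independent, the log2 fold changes had a Pearson r of 0.995 and a Spearman rho of 0.999. For OsHMGB1, the authors' log2 fold change was -2.71.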

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

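Of the alternatives below, 2 were chosen only after the data were seen, the lists without genes of other families (and the HMG-box list also without OsHMGB1) and the count without genes nearly absent in 1 genotype. OsHMGB1 stayed lower and past the threshold under all 15 alternative gene fits, with log2 fold changes from -2.63 to -2.71. The 70 named genes gave 1046 comparisons with these fits, of which 856 kept direction and side of the threshold, 178 lost the call, 12 gained it and 0 changed direction. With the replicate block, 25 of them lost the call and 1 gained it. Of the changed genes, 834 of 843 were called again with DESeq2 size factors in edgeR, 763 with library size alone, 828 without a low-count filter, 778 with a mean CPM of at least 1, 809 with DESeq2 and 734 with limma-voom. Fewer were called again with log2(FPKM + 1) (582), log2(FPKM + 0.1) (550), the replicate block (266) and without WT 1 (209), WT 2 (462), WT 3 (219), Oshmgb1 1 (521), Oshmgb1 2 (320) or Oshmgb1 3 (349). None had the other sign. The 9 list calls gave 162 comparisons, of which 121 were kept, 40 lost and 1 changed direction, and the 21 other lists gave 378, of which 15 gained a call and 43 changed direction, 0 of them past the threshold. Without the 22 genes nearly absent in 1 genotype, 821 genes changed, 297 higher and 524 lower. Where a fit left out 1 library, fewer samples lower the power. At this same number of libraries the changed genes ran from 216 without WT 1 to 649 without Oshmgb1 1, so that it also mattered which library was left out. The cause was not tested there or elsewhere. In simulations, depth and spread limited recovery to 32.8% of 1.5-fold changes with dispersions per gene.

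The number of changed genes was 295 with the replicate number as a block (122 higher, 173 lower), 164 at an adjusted p under 0.01 (53 higher, 111 lower) and 300 at a change of at least 2-fold (79 higher, 221 lower), where 3 annotation terms passed and 279 calls were shared with the authors. Higher genes numbered 483 without a low-count filter, 176 with log2(FPKM + 1) and 164 with log2(FPKM + 0.1). Leaving out 1 library gave 216 to 649 changed genes, 66 to 259 higher and 147 to 390 lower. Without WT 1 there were 216, without WT 3 226, without Oshmgb1 2 356 and without Oshmgb1 3 392.

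List results are given as adjusted p. With an estimated correlation 0 lists passed, with 0.716 for ribosomal proteins, diterpenoid phytoalexins, histones, jasmonate, light harvesting and WRKY factors, and 0.414 for HMG-box proteins, pathogenesis-related proteins and Pi scavenging. With fry, 4 lists passed, auxin response (0.0134), meristem and flower (0.0253), Pi scavenging (0.0253) and HMG-box proteins (0.0294). Ribosomal proteins, diterpenoid phytoalexins, jasmonate and WRKY factors had 0.259 in fry, histones 0.145, light harvesting 0.224 and pathogenesis-related proteins 0.0631, and the direction reversed for cytokinin (0.693) and heat shock proteins (0.799). Without genes of other families, the direction reversed for Pi transport (0.697), and Pi scavenging had 0.114. Without such genes and OsHMGB1 itself, it reversed for HMG-box proteins (0.133). With library size alone, diterpenoid phytoalexins had 0.0763, and cell wall expansion (0.957) and transposon-related genes (0.935) reversed. Without a low-count filter, Calvin cycle passed (0.0387), and cytokinin, heat shock proteins and nitrogen (0.995 each), Pi transport (0.669) and transposon-related genes (0.873) reversed. With a mean CPM of at least 1, meristem and flower passed (0.0135), and cytokinin and transposon-related genes reversed (0.823 each). With DESeq2, abscisic acid (0.0428) and Calvin cycle (0.0411) passed and transposon-related genes reversed (0.957). With limma-voom, abscisic acid, Calvin cycle and chlorophyll synthesis passed (0.0487 each), and HMG-box proteins had 0.852. With log2(FPKM + 1), diterpenoid phytoalexins had 0.0996, HMG-box proteins 0.908, Pi scavenging 0.0726, and transposon-related genes reversed (0.185). With log2(FPKM + 0.1), these were 0.085, 0.938, 0.072 and 0.166. With the replicate block, cytokinin and transposon-related genes reversed (0.994 each).

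Leaving out 1 library gave 4 lists (without Oshmgb1 1) to 11 lists (without WT 2), and 5 without WT 3. Oshmgb1 1 and WT 2 were also the libraries set apart on dimension 2 of the multidimensional scaling. The adjusted p of called lists ran from 0.000432 to 0.0808 for histones, 0.000274 to 0.0738 for light harvesting, 0.000274 to 0.177 for WRKY factors, 5.14e-05 to 0.134 for jasmonate, 8.49e-09 to 0.135 for diterpenoid phytoalexins, 0.00151 to 0.0848 for Pi scavenging and 0.00767 to 0.101 for HMG-box proteins. These calls were lost without WT 1 (WRKY 0.0544, diterpenoid 0.0633), WT 2 (diterpenoid 0.0745), WT 3 (histones 0.0808, light harvesting 0.0738, WRKY 0.0919, jasmonate 0.0558), Oshmgb1 1 (WRKY 0.177, jasmonate 0.134, diterpenoid 0.135, Pi scavenging and HMG-box 0.0848 each), Oshmgb1 2 (diterpenoid 0.0979, HMG-box 0.101) and Oshmgb1 3 (HMG-box 0.0506). Ribosomal and pathogenesis-related proteins passed in each of these 6 fits. Lists that passed in at least 1 of these fits were abscisic acid (0.0253 to 0.135), Calvin cycle (0.0112 to 0.296), chlorophyll synthesis (0.019 to 0.385) and sugar transport (0.0408 to 0.296). The direction reversed in at least 1 of these fits, always above the threshold, for cell cycle (0.474 to 0.8), cell wall expansion (0.13 to 0.976), cytokinin (0.749 to 0.934), ethylene response (0.114 to 0.8), gibberellin (0.385 to 0.976), heat shock proteins (0.394 to 0.994), nitrogen (0.541 to 0.91), guard cell and epidermis (0.225 to 0.976), Pi transport (0.8 to 0.937) and transposon-related genes (0.655 to 0.929).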

Other observations

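The gene groups of the next 2 paragraphs, adjusted over 13 groups, were chosen only after the changed genes were seen, and so were the tests for transposon release, genome segments, scaling, co-expression, other splits of the changed genes, and neighbours with informative names.

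Several groups of receptor kinases and other defence-related genes, chosen in addition to the fixed lists, held more genes that fell than rose. They are not all separate from those lists, since LOC_Os01g02730 and LOC_Os01g02700 of the LRK10 type were also counted under Pi scavenging. Because the groups were chosen from the changed genes, their tests are no independent evidence, and 3 of the 7 groups that passed with a preset correlation also passed with an estimated one. Of 72 tested wall-associated receptor kinases, 19 fell and 0 rose, with a median log2 fold change of -0.77 (camera, adjusted p = 2.49e-31, and adjusted p = 0.073 with an estimated correlation). WAK5 (LOC_Os04g24220) fell from 144 to 80.4 CPM (adjusted p = 0.00224) and WAK2 (LOC_Os09g30454) from 13.3 to 4.94 CPM (adjusted p = 0.0019). Of 125 leucine-rich repeat receptor kinases, 20 fell and 2 rose, with a median of -0.17 (adjusted p = 3.76e-09, and 0.0459 with an estimated correlation), and LOC_Os09g19229 fell from 385 to 109 CPM. Of 71 cysteine-rich and LRK10-type receptor kinases, 11 fell and 1 rose (adjusted p = 3.78e-10, and 0.073 with an estimated correlation), and LOC_Os01g02780 fell from 42.8 to 15 CPM. Of 215 resistance proteins of the NBS-LRR type, which detect pathogens inside cells, 16 fell and 2 rose (adjusted p = 0.00533, and 0.315 with an estimated correlation).

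Terpene synthases outside the diterpenoid list had 3 lower and 1 higher of 11, with a median of -1.04 (adjusted p = 8.04e-06, and 0.0459 with an estimated correlation). TPS2 (LOC_Os08g04500), described as a sesquiphellandrene synthase, fell from 502 to 152 CPM with a log2 fold change of -1.73 (SE 0.153, adjusted p = 0.00368). Germin-like proteins, of the extracellular matrix, had 4 lower and 0 higher of 18 (adjusted p = 0.000858, and 0.073 with an estimated correlation), with LOC_Os08g13440 falling from 645 to 302 CPM. Aspartic proteases of the nepenthesin type had 5 lower and 0 higher of 20 (adjusted p = 9.68e-07, and 0.0459 with an estimated correlation). These 7 groups passed with the preset correlation in each fit that left out 1 library, with at most 0.0481, for NBS-LRR proteins without Oshmgb1 1. Cytochrome P450 (5 higher, 4 lower of 116, adjusted p = 0.285), peroxidases (2 higher, 1 lower of 59, 0.285), amino acid transport (3 higher, 1 lower of 41, 0.926), chloroplast ribosomal proteins (0 of 80, 0.0956, but 0.000495 without Oshmgb1 2), mitochondrial respiration (0 of 49, 0.285) and the proteasome (1 higher, 1 lower of 59, 0.151) did not pass.

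With 6 libraries there are 10 splits into groups of 3, too few for a share under 0.05. The real split, 1 of these 10, called 843 genes and the others at most 0. For the lists, 3 of the 10 splits, the real one included, put at least 9 lists past the threshold, and the highest of the others put 10.

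Among genes nearly without reads in WT and expressed in Oshmgb1, 18 in number with folds of at least 12.9, a general release of transposon-related genes was argued against only for tested genes. The median log2 fold change of 240 tested genes, the transposon-related list and others with transposon-type names, 4 of the 18 among them, was -0.039 (SD 1.57, log2 of the smallest fold 3.69). The smallest fold came from the 18 genes themselves and sets a high bar. Of the 240 genes, 8 were higher and 11 lower, so that no common rise was seen. Some of the 240 are described as other genes, such as LOC_Os03g25600, a protein phosphatase. Of 799 matched members of the list, only 50 were tested, so that silent elements were not covered. Among the changed genes of the 240, the largest log2 fold changes were 11.2, 9.65, 8.99, 7.52, 6.71, 3.25 and 3.17 upward and -8.12 downward. This leaves release of single elements open. Reads shared between near-identical copies remain a possible explanation that could not be decided, since sequences were not compared and a shared description does not show a copy. Of the 18 genes, 11 had another gene of the same description. For 6 of them the genes of that description held at least 10 WT counts together. Of these 6, 3 carry the hAT description, which 96 genes share, with 569 WT counts together. For the other 5 the genes of the same description held 0 WT counts. Genome segments that differ between the mutant and WT plants were tested on 12 placed genes, with 1 gene kept per description. These gave 1 pair within 25 tested genes where 0.16 were expected (permutation p = 0.15), which leaves single scattered differences open. LOC_Os08g33550 and LOC_Os08g33580, which share a description, counted as 1 gene, so segments that hold genes of 1 description were not tested and stay open. A direct effect of OsHMGB1 at these genes was not tested.

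For the small opposite shifts of gene lists, scaling between the libraries was left open. Library size alone moved the median of all genes to -0.04 and left 8 of 9 called lists past the threshold, 3 higher and 5 lower. Camera compares a list with the other genes, so a shift common to all genes hardly changes its result, and the kept calls decide little. The medians of ribosomal proteins, histones and light harvesting shrank to 0.0733, 0.0625 and 0.0623 but stayed positive. Diterpenoid phytoalexins lost the call (camera, adjusted p = 0.0763), although their median went further down, from -0.33 (quartiles -0.66 and 0.02) to -0.37 (-0.70 and -0.02). A trend with expression level was examined with random lists matched on expression. Of the called lists, 2 of the 3 higher and 4 of the 6 lower had medians outside the middle 95%. Light harvesting, Pi scavenging and HMG-box proteins lay inside it. Matched medians ran from -0.0343 (diterpenoid phytoalexins) to 0.0412 (light harvesting), so that a trend may account for part of some shifts. For Pi scavenging and HMG-box proteins they were 0.00285 and 0.00412, against list medians of -0.0582 and -0.078. Expression level thus gave no shift down for these lists, although their medians lay inside the range. Variation shared by co-expressed genes between plants could not be told apart from the genotype, since only 3 libraries per genotype measure it. With an estimated correlation, 0 of the 9 called lists passed. That correlation was -0.0053 for HMG-box proteins and -0.013 for Pi scavenging, below the preset 0.01, so that shared variation does not account for their lost calls. Their unadjusted p in camera still rose, from 0.0023 to 0.033 and from 0.0021 to 0.024. The preset and the estimated setting thus differ in more than the correlation. For the other called lists the estimated correlation ran from 0.0457 to 0.375. An effect of the genotype stays open as well.

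Changed genes next to one another in the order of their identifiers were more frequent than in random orders, with 22 pairs of genes changed at least 2-fold where 3.9 were expected (permutation p = 0.0001, the smallest that these permutations can give). A segment around OsHMGB1 from another genetic background was argued against only as the source of these pairs. Of the 50 nearest tested genes, 0% were changed at least 2-fold (exact upper limit 7.11%), and 1 passed the threshold. Among all genes placed in this order 1.39% were changed at least 2-fold, so the test cannot tell whether such a segment exists. Segments elsewhere in the genome were not tested for these pairs and stay open. Families of related genes in tandem remain open. The criterion fixed first, pairs of unlike description, gave 14 pairs where 3.7 were expected (permutation p = 0.0002), but it counts related genes such as KSL5 and KSL6 and genes without an informative name as unlike, and of informative names from different families there was 1 pair (permutation p = 0.93). Of these 14 pairs, 12 changed in the same direction where 8.61 were expected (permutation p = 0.048). Since they include related genes such as KSL5 and KSL6, both lower, this cannot tell neighbouring position from gene family.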
